A study of Mus musculus with 6 samples.

How the data were processed

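C2C12 is an established line of mouse skeletal muscle precursor cells (myoblasts) that fuse into multinucleated, contractile myotubes once serum is lowered. Of the 6 arrays, 3 measured myoblasts and 3 measured myotubes. Per the labels, proliferating cells were kept in medium with 10% fetal bovine serum, and at 80 to 90% confluence differentiation was started in medium with 2% horse serum. The time spent in that medium is not given in the sources used here. The replicates were described as independent experiments, so each array was taken as 1 replicate.

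Per the labels, ribosomal RNA was removed from total RNA, and the rest was amplified with random primers along the transcripts and labelled with Cy3. The labelled RNA was hybridised to a 1-colour mouse lncRNA array, which also carries probes for coding transcripts. Each deposited scanner file holds 62939 spots, 1439 of them control spots, with intensity values for each spot. Per the file headers, the spots were read with Agilent Feature Extraction 11.0.1.1, which subtracted the local background and set its own flags for outliers, saturation and signal well above background. The array design refers to the mouse genome build mm9, per the file headers. A normalization by the authors is not stated in the labels. The deposited series table holds log2 values for 60721 probes. Set against the scanner files, each of its columns was log2 of the processed signal after signals below about 5 were raised to 1 lowest value, followed by quantile normalization. This was inferred from the values: the column median was 5.72 on each of the 6 arrays, and 13052 probes of myoblast replicate 1 shared its lowest value, against 928 in myoblast replicate 2 and 1 on each other array. The table leaves out 194 probes, among them all 15 probes with a gene accession, so it served only as an alternative source of values.

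From the scanner files, the processed intensity was taken as log2, spots flagged as outliers were left out, spots of the same probe were averaged, and the 75th percentile of each array was subtracted. All levels below are on this scale, so 0 is the 75th percentile of an array. Control spots were left out, as were 300 spots of 15 probes that carry a negative-control name without a control flag. This left 60915 probes. Probes well above background on at least 3 of the 6 arrays were tested, which kept 35487. Myotubes were compared with myoblasts with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values given for single probes come from limma. Other tables and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays limits the precision. Data were simulated for 35487 independent probes with limma's moderated SD of each probe, the same in both groups. In them 67, 67 and 66 probes were changed by 0.5, 1 and 2 on the log2 scale. The step recovered 0%, 71.6% and 97.0% of these, and 5.08% of its calls were false. The simulation leaves out that the real spread was unequal: the SD of probe differences between replicates reached 0.540 among myotubes, against 0.322 at most among myoblasts. Far more probes passed in the real comparison, which makes the Benjamini-Hochberg threshold laxer there, so these shares hold for the simulated case and not for small changes in the real one.

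Gene names were available for few probes. The scanner files name 59064 probes by a catalogue number alone and do not pair these with genes. Another 1836 probes carry a lincRNA name, which gives a class (long intergenic noncoding RNA) and a strand. The remaining 15 carry the RefSeq accession of a coding transcript, with 20 spots each, and all 15 matched 1 gene each in a RefSeq table of assembly GRCm38.p6, used for names only because it differs from the build of the array. Of 33 gene lists fixed before the data were examined (muscle differentiation, cell cycle, other cell types and others), 4 had a measured gene and 1, the reference genes commonly used to scale expression data, had at least 5. That list was tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry.

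The rule for what is named was also fixed before the data were examined: the probes or genes with the largest change in each direction among those past the threshold and well above background on all 6 arrays, the largest lower bounds among probes not well above background on every array of one group, the list members, and a fixed set of muscle, lncRNA and reference genes. The text gives fewer than the rule allows, since most of the items have no gene name. Of that fixed set, only Actb and Gapdh had a named probe. A lower bound sets the mean of the brighter group against the mean of the dimmer group after each dim array was raised to the lowest signal among probes well above background on that array.

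Scans were read from the file headers as batches: scan 1 held the 3 myoblast arrays and myotube replicate 1, while myotube replicates 2 and 3 each had a scan of their own. A fit with scan as a block therefore rests on scan 1 for the comparison. Its value for a gene is the difference within scan 1, 3 myoblast arrays against 1 myotube array, and its spread comes from the myoblasts alone, the lone myotube array being assumed to vary like them. The alternatives tried were quantile and median scaling, the deposited values, no filter, a filter on all 6 arrays, a trended and robust variance, blocks for the replicate number and the scan, other gene set tests, and leaving out each array. Added after the data were seen were normexp background correction with an offset of 50 on the median spot signals, all tested probes as the background of the gene set test (with the preset and with an estimated correlation), and catalogue probes as the class compared with lincRNA-named probes.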

Results

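The series profiled long noncoding and coding RNA in C2C12 cells before and after differentiation, with 3 myoblast and 3 myotube arrays. Of the 60915 probes, 40383, 35593 and 32051 were well above background on myoblast replicates 1, 2 and 3, and 32751, 34374 and 34813 on myotube replicates 1, 2 and 3. No spot was saturated. Across the tested probes, Pearson's r lay between 0.995 and 0.997 for pairs of myoblast arrays. It was 0.995 for myotube replicates 2 and 3, but 0.984 and 0.987 for myotube replicate 1 against these. Probes are not independent replicates, so these correlations describe the arrays only.

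The first comparison asked how far the transcripts on the array differed between myotubes and myoblasts. About as many probes were higher as lower, and the largest changes were increases. Named first are those of probes well above background on all 6 arrays. The catalogue probe ASMM10P048726 rose from −2.44 ± 0.22 in myoblasts to 6.92 ± 0.16 in myotubes (SD, n = 3 each), a log2 change of 9.36 (SE 0.15, limma adjusted p = 2.09e-07). ASMM10P025356 rose by 9.14 (SE 0.14). The largest decreases among these probes were smaller: ASMM10P010564 fell from 5.24 ± 0.06 to −0.42 ± 0.23, a change of −5.66 (SE 0.14, limma adjusted p = 4.35e-07), and ASMM10P047654 changed by −5.57 (SE 0.13). The files do not pair these numbers with genes.

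In all, 17880 of 35487 tested probes (50.4%) passed the threshold in limma, 8321 higher and 9559 lower in myotubes. Of these, 6234 changed at least 2-fold, 3210 up and 3024 down. At least 4-fold, 1130 probes rose and 807 fell; at least 16-fold, 280 rose and 170 fell; at least 64-fold, 76 rose and 5 fell. Folds of probes near background enter these counts as measured, and the excess of increases depended on them up to 16-fold. Among probes well above background on all 6 arrays, 2087 rose and 2287 fell at least 2-fold, 519 and 508 at least 4-fold, 98 and 110 at least 16-fold, and 29 and 0 at least 64-fold. The 2-fold balance also turned without myotube replicate 1 (3562 higher, 3793 lower) and with normexp background correction, chosen after the data were seen (1931 higher, 1978 lower).

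Some probes were measured in one cell state and not well above background in the other. There were 368 probes well above background on every myotube array and on no myoblast array, and 366 of them passed the threshold. For 313 of these the lower bound was at least 2-fold. The largest bound was at least 334-fold higher in myotubes (limma adjusted p = 1.08e-06) and the next at least 219-fold higher. In the other direction, 536 probes were well above background on every myoblast array and on no myotube array, of which 496 passed and 238 had a bound of at least 2-fold. The largest such bounds were at least 41.7-fold and at least 35.9-fold lower in myotubes. Among the probes that passed, 2 of each kind were lincRNA-named.

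Myotube replicate 1 shared a scan with the myoblasts, whereas myotube replicates 2 and 3 had scans of their own. With scan as a block, a fit that sets myotube replicate 1 alone against the same 3 myoblast arrays, 16906 probes passed, 13824 of them shared with the 17880 above. This overlap does not test for a scan effect, since the fits share 4 arrays. With normexp background correction, chosen after the data were seen, the count at 2-fold was 3909.

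**Figure D1:**
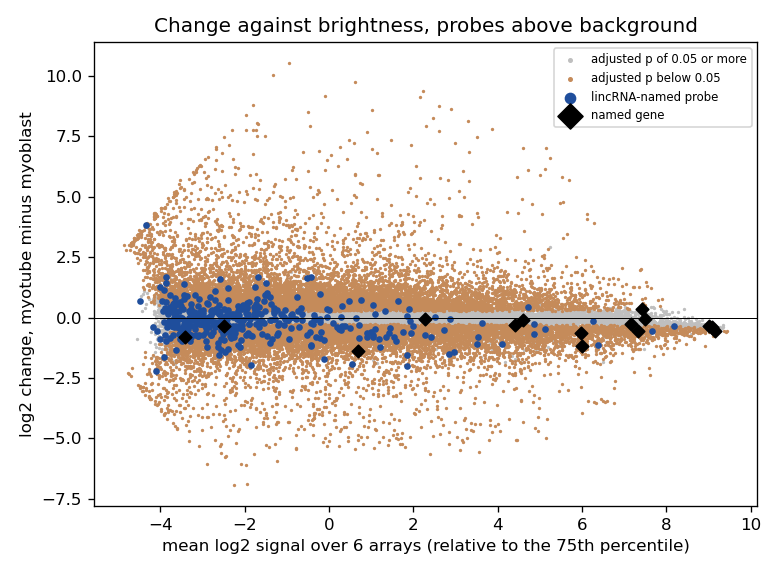
Log2 change (myotube minus myoblast, vertical axis) against mean log2 signal over the 6 arrays relative to the 75th percentile of each array (horizontal axis), 1 point per tested probe; brown points have a limma adjusted p below 0.05, grey points do not, blue points are the 389 lincRNA-named probes and black diamonds the 15 named genes. The 389 lincRNA-named probes sit mainly at the dim end, and the largest changes are increases.

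The second comparison concerned noncoding transcripts, for which the array was made, as far as their probes carry a lincRNA name. The files give no class for the catalogue probes, which can stand for noncoding or coding transcripts. Of the probes that carry a lincRNA name, 389 of 1836 were tested, against 34797 of 58141 in the main catalogue series. In myotubes 55 lincRNA-named probes rose and 88 fell. Named here are probes past the threshold among the 261 well above background on all 6 arrays. The largest increases among them were in humanlincRNA0717-, by 1.70 (SE 0.37, limma adjusted p = 0.00857), and mouselincRNA0763-, by 1.69 (SE 0.15, limma adjusted p = 0.000131). The largest decreases among them were in mouselincRNA0543-, by −2.01 (SE 0.58, limma adjusted p = 0.0250), and mouselincRNA1040+, by −1.95 (SE 0.52, limma adjusted p = 0.0185).

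Both decreases were much smaller on myotube replicate 1. The level of mouselincRNA0543- was 2.86 ± 0.32 in myoblasts (SD, n = 3) and 2.29, −0.10 and 0.36 on myotube replicates 1, 2 and 3. That of mouselincRNA1040+ was −0.86 ± 0.24 in myoblasts and −1.52, −3.69 and −3.22 in myotubes. With scan as a block the changes were −0.57 (limma adjusted p = 0.161) and −0.66 (limma adjusted p = 0.0668), so neither passed. The call of mouselincRNA0543- was also lost without myoblast replicate 2 (limma adjusted p = 0.0635), myoblast replicate 3 (0.0687), myotube replicate 2 (0.0757) or myotube replicate 3 (0.0947). That of mouselincRNA1040+ was lost without myoblast replicate 1 (limma adjusted p = 0.0510), myoblast replicate 3 (0.0514), myotube replicate 2 (0.0546) or myotube replicate 3 (0.0749). Without the filter on dim probes both missed the threshold (limma adjusted p = 0.0665 and 0.0524). The 2 increases passed under every alternative run, but their size varied. humanlincRNA0717- stood at −0.52 on myotube replicate 1 against 0.89 and 0.88 on the others, and its change was 0.76 with scan as a block (limma adjusted p = 0.0206). With normexp, chosen after the data were seen, the change of mouselincRNA0763- was 1.01 (limma adjusted p = 0.000205).

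Counted together, 143 of 389 lincRNA-named probes passed (36.8%), 39 of them with at least a 2-fold change (15 up, 24 down). Among the catalogue probes 17597 of 34797 passed (50.6%), an odds ratio of 0.568 (95% interval 0.459 to 0.702, Fisher's exact test, two-sided p = 5.56e-08). Catalogue probes have no stated class, so these shares do not compare noncoding with coding transcripts. Probes on the same arrays are not independent replicates, so the intervals and p-values for shares of probes describe probes and not cultures. The catalogue probes as comparison class and the matching that follows were chosen after the data were seen. The lincRNA-named probes were dimmer, so 10000 random lists of catalogue probes were matched to them on brightness. On average 46.9% of a matched list passed, with 95% of lists between 41.9% and 51.7%. No list was as low as the lincRNA-named probes, and the permutation p was then set to a lower limit of 1e-04. Against the 15 named coding genes, 8 of which passed when adjusted over all probes, the difference missed the threshold (odds ratio 0.510, 95% interval 0.154 to 1.65, Fisher's exact test, two-sided p = 0.276). Falls outnumbered rises more than among catalogue probes, with 38.5% of the changed lincRNA-named probes higher against 46.7%, a difference that missed the threshold (Fisher's exact test, two-sided p = 0.0528). The balance of the 2-fold count turned with scan as a block (20 up, 19 down) and without myotube replicate 2 (18 up, 16 down). Without myotube replicate 1 the count at 2-fold was 63, and with normexp, chosen after the data were seen, it was 14.

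The lincRNA-named probes came from 3 series. In the mouselincRNA series 24 of 136 tested probes rose and 31 fell (40.4% changed). In the humanlincRNA series 24 of 221 rose and 47 fell (32.1% changed). In the MM9LINCRNAEXON series 7 of 32 rose and 10 fell (53.1% changed). The share of this last, small series was not below the 50.6% of the main catalogue, and at 2-fold it was 28.1% against 17.7%. The lower share of lincRNA-named probes thus came from the other 2 series. Differences between the series were not tested. A smaller catalogue series had 44 of 286 probes higher and 88 lower. Its share of changed probes, 46.2%, was below that of the main catalogue, a difference that missed the threshold (Fisher's exact test, two-sided p = 0.138).

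Many lincRNA numbers carried a probe for each strand. Of 876 such pairs, both strands were tested in 43, 1 strand in 276 and neither in 557. Both were tested about as often as the separate shares would give (37.3 pairs, Fisher's exact test, two-sided p = 0.257). Over the 43 pairs the changes of the strands showed no relation that passed a test, with Pearson's r of −0.02 (permutation p = 0.865) and Spearman's rho of −0.09 (permutation p = 0.576). Leaving out the 2 farthest pairs gave r = −0.07. In 7 pairs both strands passed the threshold, 4 of them in the same direction. The pairs are not independent replicates.

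The third comparison concerned the 15 genes with named probes, most of them housekeeping genes. In myotubes 8 were lower and 1 was higher, adjusted over the list alone, with Ppia turning under quantile normalization; adjusted over all probes tested, 7 were lower and 1 was higher. Actb, which encodes cytoplasmic beta-actin, fell from 6.58 ± 0.12 to 5.39 ± 0.47 (SD, n = 3 each), 2.28-fold (log2 change −1.19, SE 0.23, limma adjusted p = 0.00481), and was lower on 3 of 3 myotube arrays. G6pd2, an intronless copy of the gene for glucose-6-phosphate dehydrogenase, was 2.62-fold lower (log2 change −1.39, SE 0.11, limma adjusted p = 9.4e-05). Whether its probe also binds the transcript of the parent gene G6pdx was not tested, so the identity of this signal is uncertain. Hsp90ab1, a cytosolic chaperone, rose by 0.36 (SE 0.12, limma adjusted p = 0.0360).

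Rpl13a, a protein of the large ribosomal subunit, fell by 0.64 (SE 0.10, limma adjusted p = 0.00339) and Hprt, an enzyme of purine salvage, fell by 0.56 (SE 0.12, limma adjusted p = 0.00701). The alpha-tubulin gene Tuba1b changed by −0.58 (limma adjusted p = 0.0164), the cyclophilin gene Ppia by −0.34 (0.0439; 0.10 under quantile normalization) and the glycerol kinase gene Gk by −0.34 (0.0356). Ldhal6b, a relative of lactate dehydrogenase A, was not well above background on any myotube array and was at least 1.58-fold lower there (limma adjusted p = 0.00339), a log2 bound of 0.656. Its change fell short of that bound with scan as a block (−0.59) and with normexp, chosen after the data were seen (−0.37). The other alternatives that held this gene gave falls larger than the bound. The other 6 genes did not pass: Gapdh of glycolysis (−0.41), the lysosomal beta-glucuronidase gene Gusb (−0.30), the MHC class I light chain gene B2m (−0.25), Nono (−0.10), Tbp (−0.07) and the transferrin receptor gene Tfrc (−0.04), of which Gapdh, B2m, Nono and Tfrc were above 0 under quantile normalization.

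**Figure D2:**
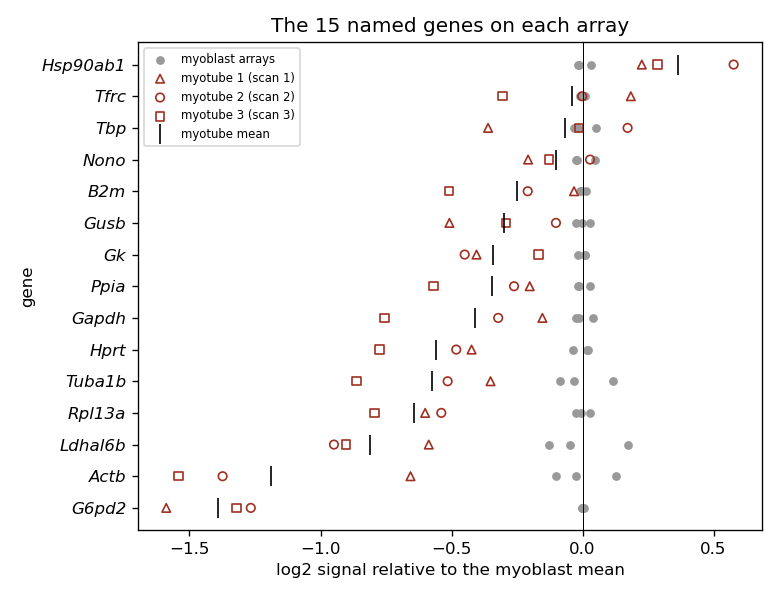
Log2 signal of each of the 15 named genes on each of the 6 arrays, relative to the mean of its 3 myoblast arrays (horizontal axis); grey points are myoblast arrays, open symbols are myotube replicates 1, 2 and 3 with their scans, and the vertical bar is the mean of the myotubes. Actb and G6pd2 lie lowest, and Hsp90ab1 alone lies above the myoblasts on 3 of 3 myotube arrays under the 75th percentile scaling.

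Several of these calls were narrow. Under quantile normalization Ppia turned to 0.10 (limma adjusted p = 0.515), Tuba1b missed the threshold at −0.14 (0.233) and Tfrc passed it at 0.27 (0.0292), and Gapdh, B2m and Nono, which had not passed, changed sign (0.02, 0.02 and 0.03). Of genes that kept their call in it, Hprt was at −0.28 (limma adjusted p = 0.0354), Rpl13a at −0.45 (0.0115) and Hsp90ab1, with a larger rise, at 0.67 (0.0174). With scan as a block, which for these genes is the difference within scan 1, Ppia (−0.20, limma adjusted p = 0.0633), Tuba1b (−0.35, 0.0522) and Hsp90ab1 (0.23, 0.0522) no longer passed. The spread in that fit comes from the myoblasts alone. Gusb (−0.51, 0.0108) and Tbp (−0.36, 0.0212) passed in it, but for Tbp only myotube replicate 1 (1.96) lay below the myoblasts (2.29 to 2.37), against 2.49 and 2.31 on replicates 2 and 3. Actb was at −0.66 (limma adjusted p = 0.0126) and G6pd2 at −1.59 (0.000320). Without myoblast replicate 1 the count of changed genes was 5, with Ppia, Gk, Tuba1b and Hsp90ab1 past the threshold no longer (limma adjusted p = 0.128, 0.110, 0.0675 and 0.110). Ppia, Gk and Hsp90ab1 also missed it without myoblast replicate 2 (0.110, 0.0926, 0.0926), myoblast replicate 3 (0.111 each) or myotube replicate 2 (0.0624, 0.0718, 0.0668). Without the filter on dim probes the same 3 genes missed it (0.0857, 0.0752, 0.0752). Without myotube replicate 3, Ppia (0.0854) and Hsp90ab1 (0.0515) missed it. B2m (0.0244) and Gapdh (0.0160) passed without myotube replicate 1, and Gusb (0.0323) without myotube replicate 2. Gapdh (0.0495) and Gusb (0.0481) also passed with trended, robust variance, and Gapdh (0.0308) with normexp, chosen after the data were seen.

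Of the gene lists, only that of reference genes could be tested, with 9 measured members. Adjusted over the list alone, here these 9 genes, Actb, Rpl13a and Hprt fell and none rose. Ppia, which passed when adjusted over the 15 named genes, did not pass over the 9. The median of the list was −0.34. Against the other 6 named genes the list did not stand apart in camera (p = 0.932, p = 0.956 with an estimated correlation), whose direction was upward although the median lies below 0. Those 6 genes include G6pd2, the largest fall of the named genes. So small a background could hardly show a shift, and camera's result is no evidence against one. With limma's fry, which asks whether the members moved one way on balance, the list was lower (adjusted p = 0.0125). In limma's camera against all tested probes, a background chosen after the data were seen, it was lower at the preset correlation (adjusted p = 0.0439), a call that was lost with an estimated correlation (adjusted p = 0.365). The other lists with a measured gene had 1 each: Actb in the actin cytoskeleton list, which fell, Rpl13a among cytosolic ribosomal proteins, which fell, and B2m in the interferon list, which did not pass.

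Control spots for the ends of transcripts were compared beside these genes. The gap between the ends can depend on the RNA and its labelling. It also sets different probes against each other, which for Pgk1 were of unlike brightness (8.43 at the 3' end and 0.74 at the 5' end in myoblasts). Effects of the RNA, of brightness and of the scans were not told apart. The signal of the 3' spots of Gapdh exceeded that of its 5' spots by 1.09 ± 0.03 in myoblasts and 0.86 ± 0.17 in myotubes (log2, SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). For Pgk1 the gap was 7.69 ± 0.13 and 7.22 ± 0.42 (exact permutation test, two-sided p = 0.2). Myotube replicate 1, at 1.05 and 7.70, lay near the myoblasts, and myotube replicates 2 and 3 lay lower, at 0.80 and 0.72 for Gapdh and 7.09 and 6.89 for Pgk1.

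**Figure D3:**
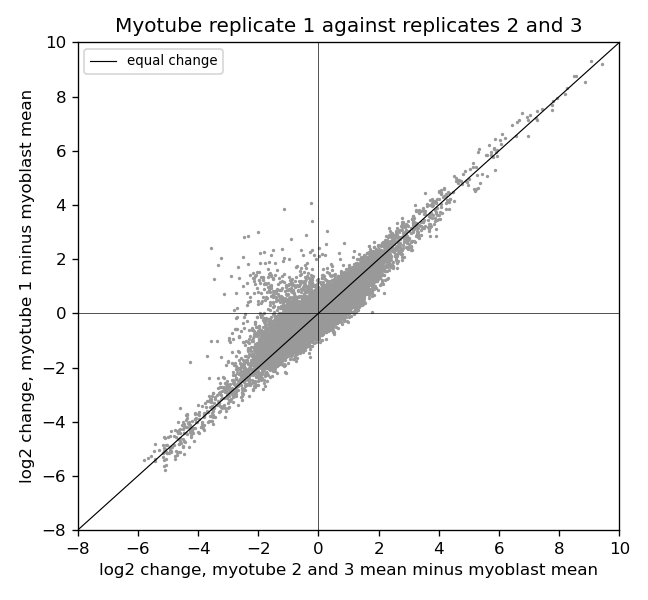
Log2 change of myotube replicate 1 against the myoblast mean (vertical axis) plotted against the change of the mean of myotube replicates 2 and 3 (horizontal axis), 1 point per probe well above background on all 6 arrays (29808 of 29862, leaving out 54 with a flagged spot on some array); the diagonal marks equal change. Most points follow the diagonal, and a cloud above it, with 69 points over 2-fold up in replicate 1 and over 2-fold down in the others, departs from it.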

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

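The tests of the 69 probes and of the scans, the estimates with replicates 2 and 3 set apart and the bootstrap interval under quantile normalization were chosen after the results were seen.

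Apart from the bright corner spots that mark the grid, 9 of the control probes that name no mouse gene gave signal well above background on at least 90% of their spots. The mean level over the 6 arrays was 0.669 for ERCC-00062_278, a probe for a synthetic spike-in. It was 1.14 ± 0.03 in myoblasts and 0.20 ± 0.38 in myotubes (SD, n = 3 each). Myotube replicate 1, which shared its scan with the myoblasts, stood at 0.62, and myotube replicates 2 and 3 stood at −0.11 and 0.08. Cell state and scan cannot be told apart in this difference. The other 11 probes of that spike-in set were well above background on 0.952% to 56.7% of their spots. Probes written for human genes stood at 8.02 and 3.71 for the 3' and 5' ends of GAPDH and at 7.19 and −1.22 for those of PGK1. Those for rat genes stood at 4.76 and 4.91 for GAPDH and at −1.88 and 0.733 for PGK1. The 15 negative-named probes had means between −6.06 and −4.93, with 4.83% of their spots well above background.

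Myotube replicate 1 lay somewhat closer to the myoblasts than the other myotubes: the SD of its probe differences to the myoblast mean was 1.04, against 1.12 and 1.08. A share of myoblast RNA in that sample was estimated from probes over 4-fold up in replicates 2 and 3 (0.0349, 95% bootstrap interval 0.00799 to 0.0695) and from probes over 4-fold down (0.0269, 0.0192 to 0.0320), which differ by 0.00803. The intervals overlap above 0, the outcome set beforehand for such a share, and neither other replicate gave that when set apart (risers −0.0717 and fallers 0.00171 for replicate 2, 0.103 and −0.00704 for replicate 3). The intervals resample probes and hold no spread between arrays. The riser estimates of replicates 2 and 3 were larger in size than that of replicate 1, so the riser share cannot be told from variation between arrays. Their faller estimates were smaller in size than that of replicate 1. A small share of myoblast RNA may be part of the pattern, but the evidence from the risers was weak: 54.4% of 540 lay closer to the myoblasts on replicate 1, against 71.9% of 615 fallers, and the median rise of the risers was 2.73 on it against 2.71 in replicates 2 and 3. Differences between scans in general stay open. The SD of probe differences was 0.297 between replicates 2 and 3, also on different scans. It was 0.540 between replicates 1 and 2 and 0.485 between replicates 1 and 3. The ratio to the smaller of these, 0.613, lay between the bounds set for and against. A ratio to the larger would be lower, so this reading rests on that choice. A slide or scan effect shared with the myoblasts cannot be told apart from a weaker response of that culture, since scan 1 holds 1 myotube array. The bright corner spots, which measure no mouse gene, went with the scan. They stood at 7.76, 7.83 and 7.99 on the myoblast arrays and 7.79 on myotube replicate 1, against 6.96 and 6.75 on myotube replicates 2 and 3. Signals at the bright end thus differed between scans, and how far this reached other probes was not tested.

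Part of the distance of myotube replicate 1 took another form: 69 probes were over 2-fold above the myoblast mean on it and over 2-fold below that mean in replicates 2 and 3, against at most 2 probes when another myotube array was set apart, and none of the 69 passed the test between groups. Mixing with myoblast RNA gives values between those of its sources, so it does not account for these 69. The myoblast arrays, all on scan 1, had a median range of 1.33 on these probes (log2), against 0.09 to 0.13 for lists matched on brightness, so the probes varied within a scan too, but the range among the myotubes on 3 scans was 3.73 and a contribution of the scans stays open. A candidate explanation is 1 set of transcripts whose amount varied between cultures or RNA preparations of both groups: of these probes, picked without regard to the order of the myoblast arrays, 92.8% (64 of 69) were higher on myoblast replicate 2 than on replicate 1, against 45.1% of all probes. Whether the variation was in the cells or arose in RNA isolation or removal of ribosomal RNA was not tested, because the files do not pair the probes with genes.

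The 15 named genes were mostly lower in myotubes, with a median of −0.34 and 14 of 15 below 0. A trend shared by other bright probes could account for this: among 10000 lists matched on brightness the median of the 15 genes stood at percentile 43.6, and the brightest 3549 tested probes had a median change of −0.29. The scaling stays open as well, since quantile normalization moved the median to −0.139 (95% bootstrap interval −0.33 to 0.02) with 9 of 15 below 0, whereas median scaling left it at −0.35. Quantile normalization moved bright genes upward, such as Gapdh from −0.41 to 0.02 and Ppia from −0.34 to 0.10. It hardly moved the dim genes Gk (−0.34 to −0.33) and Ldhal6b (−0.81 to −0.79). The scaling and the trend with brightness are therefore not separate explanations here. A biological fall of these genes in myotubes stays open and was not tested apart from the trend.

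Other splits of the 6 arrays into 3 and 3 number 10 with the real split, too few for a share under 0.1. The real split gave 17880 changed probes, 143 changed lincRNA-named probes and 9 changed genes, the highest other split gave 0 of each, and 1 of the 10 splits, the real one, reached these counts. Every other split puts arrays of both cell states into each part, which widens the spread within parts. Few or no calls were therefore to be had from them, and their 0 counts are no evidence for the real split.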

How the results depend on the processing

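The normexp setting and the all-probe background were chosen after the data were seen. The count of 17880 changed probes ranged from 14457 (no filter on dim probes) to 18318 (trended, robust variance) under other settings, and from 13566 to 22931 with 1 array left out, the highest without myotube replicate 1. The count at 2-fold was 3909 with normexp on the median spot signals, and 5786 to 7355 with 1 array left out. The normexp offset of 50 is about as large as the median processed signal of the arrays (46.3 to 72.9), so it shrinks folds of dim probes. With normexp the dim Ldhal6b went from −0.81 to −0.37 and mouselincRNA0763- from 1.69 to 1.01. The bright Actb hardly moved (−1.19 to −1.16). How much of the lower count came from the offset was not tested. Changed lincRNA-named probes numbered 107 to 143 under other settings and 99 to 194 with 1 array left out. Changed genes numbered 6 to 11 under other settings and 5 to 11 with 1 array left out, with 5 without myoblast replicate 1; the cause was not tested. Lists shifted were 1 with fry and 1 with all tested probes as background at the preset correlation, against 0 in every other run; these tests ask other questions. Under quantile normalization Ppia reversed (0.10), as did Nono (0.0325), B2m (0.0211), Gapdh (0.0159) and Tfrc (0.27), which had not passed. All of these are bright genes, which that scaling moved upward. Why bright probes were lower in myotubes before it was not tested. Tfrc was also above 0 with scan as a block (0.18) and normexp (0.00637). With 1 array left out, Tfrc ranged from −0.15 to 0.0913 (without myotube replicate 3) and Tbp from −0.19 to 0.0787 (without myotube replicate 1). Of 329 values of the 23 named items under the alternatives, 275 kept direction and side of the threshold, 37 lost the call and 8 gained it in the same direction. In 9 the sign changed, 8 of them values of genes that had not passed.

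The replicate numbers did not pair the samples: correlations of deviations between same-numbered arrays were −0.15, −0.00337 and −0.09, and not every array correlated best with its own number. With the replicate number as a block, 16538 probes, 138 lincRNA-named probes and 6 genes passed, Ppia, Gk and Hsp90ab1 missing the threshold (adjusted p = 0.0589 each in limma). Normexp on the mean spot signal was not run, because the files used here hold median signals in its place, and averaging several probes of a gene was not run, because each named gene has 1 probe. The deposited values hold no named genes and gave 17793 changed probes. Signal over background limits the lincRNA-named probes, of which 389 of 1836 could be tested. These probes include 876 pairs with a probe for each strand, so the share tested is not a share of lincRNAs expressed.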

Other observations

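The tests in this part were chosen after the data were seen. Probes that varied widely between replicates of one cell state tended to vary in the other too. Of 29862 probes well above background on all 6 arrays, 54 with a flagged spot on some array were left out. Of the other 29808, 303 ranged over more than 2-fold among the myoblasts and 1236 among the myotubes. Both held for 111 probes, against 12.6 if the groups were unrelated. Of these 111 probes, 60 had myoblast replicate 2 highest and 1 lowest together with myotube replicate 1 highest and 2 lowest, an order seen in 2.24% of the 29808 probes. That order is also the order of the mean levels of the 69 probes described above. Those 69 had a median myoblast range of 1.33 (log2), so the 2 sets overlap, by how many probes was not counted. The count of 60 is therefore not evidence separate from the 69 probes. Only 3 of the 111 passed the test between groups, and 2 were lincRNA-named.

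Catalogue probes with consecutive numbers had related changes. Across 22592 neighbouring pairs, Pearson's r of the log2 change was 0.168, against at most 0.0198 in 1000 shuffles. It was 0.0894 at a distance of 2 numbers, 0.0300 at 5 and 0.00395 at 20. Among 20242 neighbours whose spots lay more than 20 rows apart on the slide, r was 0.165. Of 292 probes that changed over 16-fold and had a neighbour measured, 88 (30.1%) had a next number changed at least 2-fold in the same direction, against 9.21% of all such probes that were at least 2-fold higher and 8.84% that were lower.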
